A study of Homo sapiens with 7 samples.

How the data were processed

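The series holds 7 RNA sequencing libraries of the human renal carcinoma line 769-P, 3 of PA cells and 4 of Lat-M cells. Per the labels, total RNA was isolated with an RNeasy kit and libraries were made with the TruSeq RNA v2 kit or the NEBNext Ultra kit, and which kit made which library is not stated. The submitters' processing notes name TopHat2 2.2.4 and the genome hg19 without further settings. The deposited files give TPM per gene, a unit read from the values themselves: each library sums to 1e+06 over all listed genes, short and non-coding RNAs included, and the lowest value above 0 of a gene in the low range (mean under 0.1 TPM) decreases with transcript length (Spearman's rho -0.94 across 7767 genes). The submitters' quantifier, annotation and filters are not stated. TPM keeps no read counts, so depth, counting intervals and detection floors are unknown.

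Values were taken as log2(TPM + 1), and the 16724 genes with a mean of at least 1 TPM over the 7 libraries were tested with limma (version 3.58.1, R 4.3.3; linear models with the trend and robust options), with Benjamini-Hochberg adjustment at 0.05. Errors beside log2 fold changes are standard errors, and errors beside TPM are standard deviations between libraries. The log2 fold changes of genes near 0 TPM depend on the 1 that was added. Lat-M was compared with PA in a fit of 2 groups. Lat-M1 with PA, Lat-M2 with PA and Lat-M2 with Lat-M1 were compared in a fit of 3 groups that share 1 estimate of spread. Genes changed alike are those past the threshold in the same direction in both Lat-M pairs against PA, set beside the product of the separate counts over the number of genes and beside 20 simulations of unchanged groups that share the PA libraries. The groups, the gene lists, the tests by gene and the list tests of Lat-M against PA and of Lat-M2 against Lat-M1 were fixed before the data were examined. Last numbers of the library names did not pair the libraries: after group means were taken off, correlations of libraries of the same last number were -0.082 to 0.0312.

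Gene symbols are those of the files, which list genes by Ensembl identifier and symbol. For 161 symbols under more than 1 identifier, AQP1 and ITGB3 among them, the entry with the highest mean was used. Gene type, length, GC content, chromosome and gene order came from GENCODE v29 by Ensembl identifier, which matched 30947 of the listed genes and 94.2% of the tested genes. That annotation is of another genome build than the submitters', so no positions are given.

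The genes named were chosen by rule. For Lat-M against PA these were the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap and whose higher group averaged at least 5 TPM, up to 4 members with the smallest p of each list that camera called or that had at least 3 changed members, and VHL, HIF1A, EPAS1, PBRM1, SETD2, BAP1, PAX8, SOX2, SOX9, DKK1 and MKI67 whatever their result, of which DKK1 was not among the listed genes. For the other comparisons these were the 5 largest rises and falls by the same rule. Further list members are given as examples chosen after their values were seen.

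Of 36 gene lists, 31 had at least 5 tested members and were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, which asks whether the genes of a list move one way on balance. The lists cover HIF targets, glycolysis, the nuclear-encoded respiratory chain, mitochondrially encoded genes, cholesterol synthesis, fatty acid synthesis and desaturation, fatty acid oxidation, NRF2 and glutathione, the amino acid and ATF4 response, endoplasmic reticulum stress, mesenchymal markers, epithelial markers, proximal tubule markers, TGF-beta targets, YAP and TEAD targets, WNT pathway and inhibitors, metastatic latency and dormancy, S phase, G2 and mitosis, p53 targets, MYC and ribosome biogenesis, the interferon response, MHC class I and antigen processing, NK cell ligands, NF-kB and cytokines, extracellular matrix, integrins and cell adhesion, receptor tyrosine kinases and ligands, MAPK output, cytosolic ribosomal proteins and replication-dependent histones. Untested lists were markers of fibroblasts and pericytes, endothelium, leukocytes, erythroid cells, and neural and glial cells. Of 744 genes on the lists, 37 were not listed in the files by symbol.

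Alternatives were a pseudocount of 0.1, no filter on low values, a minimum mean of 5 TPM, at least 2-fold changes, a test against a 1.5-fold change (limma's treat), leaving out each library in turn, and for Lat-M against PA a contrast within the fit of 3 groups, limma's duplicateCorrelation (statmod 1.5.0), averaged libraries and the last number as a block. For Lat-M2 against Lat-M1 they were the Lat-M libraries alone, with and without that block. Scaling by the median ratio, rescaling protein-coding genes alone to the same sum, leaving out 4 structural RNAs and rescaling the rest to the same sum, list tests of Lat-M1 and of Lat-M2 against PA, and removal of trends on GC content and transcript length (splines of 4 degrees of freedom) were chosen after seeing the data, as were tests of structural RNAs, of fibroblast markers, of another cell line and of runs of neighbouring genes.

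The method was tested on simulated data of the same size, 1 set per comparison, in which 50 genes changed by each of 4 folds. It was not tested on changed genes whose mean log2(TPM + 1) corresponded to less than 5 TPM, as none were drawn from those. In the order Lat-M against PA, Lat-M1 against PA, Lat-M2 against PA and Lat-M2 against Lat-M1, it recovered 36%, 88%, 78% and 74% of changes of 1.5-fold and 88%, 96%, 98% and 96% of changes of 2-fold, and 3.09%, 8.7%, 7.43% and 7.58% of the genes called were unchanged. The 8.7%, 7.43% and 7.58% exceeded the rate that the adjustment was set to. In the real data, libraries of a Lat-M number were correlated (consensus 0.598). How often unchanged genes are called under that correlation was not tested, so the 3.09% may be too low for Lat-M against PA. A list lowered by 0.3 on the log2 scale was the only 1 of 31 called. The simulated genes varied independently, while the estimated correlation within the p53 targets was 0.404 in Lat-M2 against PA. The simulation therefore does not show how often camera calls unchanged lists of correlated genes. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6.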

Results

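RNA sequencing measured gene expression in 7 libraries of 769-P, an established human cell line of clear cell renal cell carcinoma. There were 3 libraries of PA cells, an abbreviation that the labels do not expand, and 4 libraries of Lat-M cells, which the labels describe as latent metastatic. The Lat-M libraries carry the numbers 1-1, 1-2, 2-1 and 2-2. They are called Lat-M1 (1-1 and 1-2) and Lat-M2 (2-1 and 2-2) below, although the labels do not say what the first number stands for. Expression is given as TPM, a measure of transcript abundance scaled to the same sum in each library, and 16136 to 16872 genes reached 1 TPM in a library. TPM keeps no read total, so the depth of the libraries is unknown. Whether the replicates were separate cultures is not stated. Each p-value of a single gene therefore measures only the spread between these libraries, which may be technical. Camera compares the genes of a list with the other genes, and p-values of chromosomes come from random sets of genes. Genes are not independent replicates.

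The libraries formed 3 groups. Pearson's r across the tested genes, which are not independent replicates, was at least 0.9834 within PA, Lat-M1 and Lat-M2. It was 0.9745 to 0.9779 between Lat-M2 and PA, and 0.9383 to 0.9445 between Lat-M1 and PA. The first principal component held 58% of the variance and set Lat-M1 apart, and the second held 16.8% and set Lat-M2 apart from PA. The structural RNAs RN7SL1, RN7SL2, RN7SK and RMRP, of the signal recognition particle, the 7SK particle and RNase MRP, took 30.5 ± 1.17% of all TPM in PA (SD, n = 3), 20.2 ± 2.29% in Lat-M1 (n = 2) and 25.3 ± 3.42% in Lat-M2 (n = 2). Protein-coding genes took 54.0 ± 0.656%, 63.2 ± 2.29% and 58.4 ± 3.88%. The median log2 fold change of all tested genes was accordingly above 0 against PA, at 0.15 for Lat-M, 0.16 for Lat-M1 and 0.14 for Lat-M2, and it was -0.011 for Lat-M2 against Lat-M1. Counts after scaling each library by its median ratio to the other libraries, which removes this shift, are therefore given beside the unscaled counts.

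The comparison of Lat-M with PA asked which transcripts set the latent metastatic cells apart. SPARC, a matrix glycoprotein, was at 0.0827 ± 0.0447 TPM in PA (SD, n = 3), 9.19 ± 1.06 TPM in Lat-M1 (n = 2) and 9.54 ± 0.807 TPM in Lat-M2 (n = 2), a log2 fold change of 3.26 ± 0.12 (SE; limma adjusted p = 0.00022). VCAM1, a cell adhesion molecule that binds integrins on leukocytes, rose from 3.74 ± 0.338 to 76.6 ± 0.843 and 39.2 ± 3.63 TPM (log2 fold change 3.56 ± 0.28, limma adjusted p = 0.00356). TNFAIP6, a secreted hyaluronan-binding protein, rose from 2.2 ± 0.157 to 43 ± 1.72 and 29 ± 3.28 TPM (3.51 ± 0.18, limma adjusted p = 0.000866). PTRF, a coat protein of caveolae, had the largest rise, from 0.162 ± 0.127 to 64.5 ± 0.983 and 14.2 ± 1.82 TPM (4.77 ± 0.61, limma adjusted p = 0.0239). Among the falls, MMP1, an interstitial collagenase, went from 521 ± 17.5 to 16.4 ± 1.29 and 90.7 ± 6.65 TPM (-3.71 ± 0.68, limma adjusted p = 0.0441). LTB, a cytokine of the tumour necrosis factor family, went from 11.6 TPM to 2.03 and 2.06 TPM (-2.05 ± 0.14, limma adjusted p = 0.00224).

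The other genes named by size of change, 8 up and 10 down, came from several families. The rises were SGPP2, a sphingosine-1-phosphate phosphatase (3.93 on the log2 scale), DSC2, a desmosomal cadherin (3.88), CD74, the invariant chain of MHC class II (2.96), POF1B (2.95), POU3F3, a transcription factor (2.74), TIMP3, an inhibitor of metalloproteinases (2.72), DDR1, a collagen receptor (2.64), and FSTL1 (2.43). The falls were EDIL3, a secreted integrin ligand (-3.43), AL590369.1 (-3.43), PTGES, a prostaglandin E synthase (-3.31), GABRB1, a receptor subunit for GABA (-3.03), RP11-731J8.2 (-2.26), PEG10, a gene derived from a retrotransposon (-2.17), PRR16 (-2.12), MIR205HG (-1.94) and SLC9A2, a sodium and proton exchanger (-1.78). ZBED2 completed the falls (-1.73 ± 0.18, limma adjusted p = 0.00937). Scaling ended the calls of TIMP3 (limma adjusted p = 0.0598), FSTL1 (0.0711), MMP1 (0.0598), AL590369.1 (0.0635) and PTGES (0.0627).

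In all, 485 of 16724 tested genes differed between Lat-M and PA, 420 higher and 65 lower, and 121 of them by at least 2-fold (89 higher, 32 lower). After scaling there were 208, 113 higher and 95 lower (52 and 29 by at least 2-fold), and 167 genes were called both ways. The 4 Lat-M values lay entirely above or below the 3 PA values in 28.5% of genes (23.2% scaled). Chance would give 5.7% if the 7 libraries were exchangeable, but libraries of a Lat-M number were correlated (consensus 0.598), so the share that chance gives here is not known. The count was 26, 18 and 20 without PA 1, PA 2 and PA 3, 50 without Lat-M 1-1, 49 without 1-2, 92 without 2-1 and 1861 without 2-2, and of the 24 genes named by size 18, 19 and 19 lost their calls without PA 1, PA 2 and PA 3, 13 without 1-1, 13 without 1-2, 8 without 2-1 and none without 2-2. LTB, MIR205HG, SPARC, TNFAIP6 and VCAM1 kept their calls in all 7 of these fits, which still counted libraries of a Lat-M number as independent. Each lost its call under at least 1 other alternative (highest limma adjusted p = 0.113, 0.113, 0.0739, 0.113 and 0.198). Changed genes numbered 6106 when Lat-M1 and Lat-M2 were fitted as separate groups, 88 when libraries of a number were treated as correlated repeats and 3 when they were averaged. With the last number of each library as a block there were 0, where limma left 2060 genes at an unadjusted p under 0.05.

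**Figure D1:**
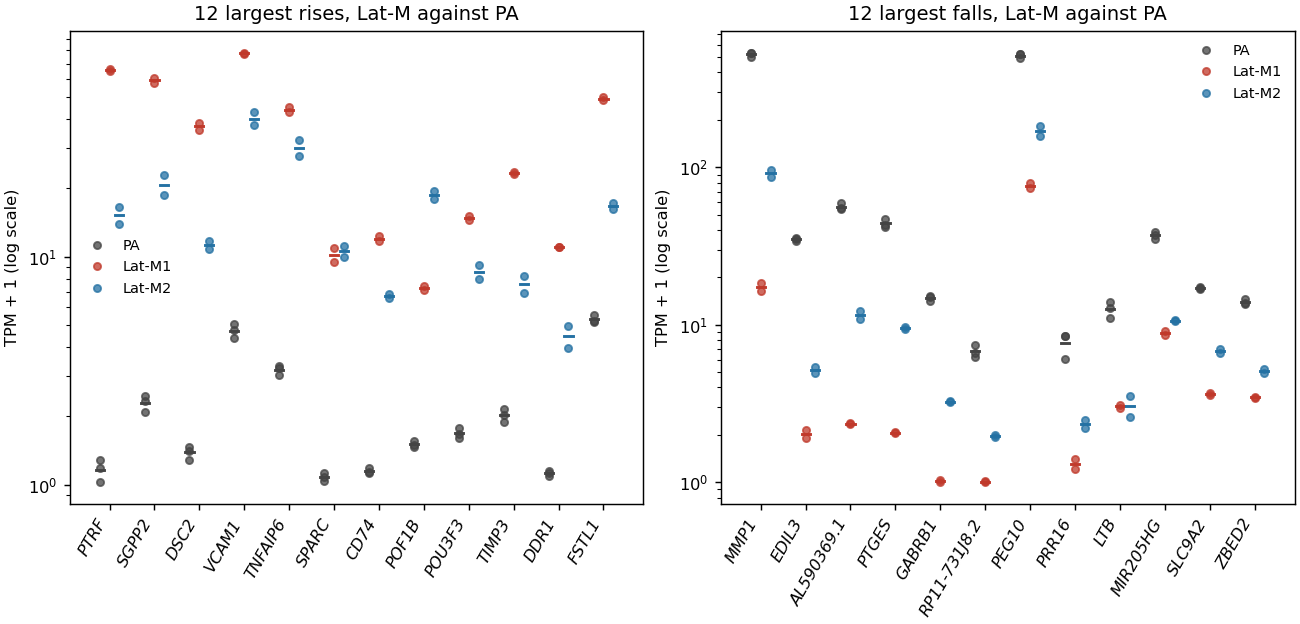
TPM + 1 on a log scale in each of the 7 libraries for the 12 largest rises and 12 largest falls in Lat-M against PA, with a point per library and a short line at each mean of PA, Lat-M1 and Lat-M2. SPARC averaged 0.0827 TPM in PA and 9.19 and 9.54 TPM in Lat-M1 and Lat-M2, and MMP1 521, 16.4 and 90.7 TPM.

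Of 31 gene lists tested, 6 moved against the other genes in Lat-M compared with PA by camera. All 6 had an adjusted p = 0.851 with an estimated correlation. Of the 6, fry called only MYC and ribosome biogenesis (fry adjusted p = 0.0475). The fry adjusted p was 0.0788 for TGF-beta targets, 0.1065 for MHC class I, 0.1126 for NF-kB, 0.6428 for proximal tubule markers and 0.9716 for fatty acid oxidation. TGF-beta targets had 3 of 18 members higher (4 adjusted over the list alone) and none lower: TIMP3, SMAD7, an inhibitor of the pathway (0.56 ± 0.097), and SKIL, a SMAD corepressor (0.44 ± 0.070; camera adjusted p = 0.0278). NF-kB and cytokine genes had 1 of 18 higher, the chemokine CXCL2 (1.43 ± 0.26; 6 adjusted over the list alone; camera adjusted p = 0.0278). CCL2, another chemokine, stood at 2.98 TPM in PA, 38.8 in Lat-M1 and 10.1 in Lat-M2 (limma adjusted p = 0.0618). MHC class I and antigen processing genes had none of 17 past the test over all genes and 1 adjusted over the list alone, with a median log2 fold change of 0.61 (camera adjusted p = 0.0278). MYC and ribosome biogenesis genes had 3 of 20 higher (10 adjusted over the list alone), namely NOP16 (0.56), PA2G4 (0.44) and MYC (0.41), and the list's call ended on scaling (camera adjusted p = 0.034, and 0.0583 scaled). After scaling no TGF-beta or NF-kB member passed, while both lists kept their camera calls. Scaling gave camera calls to the respiratory chain, down (scaled adjusted p = 0.000541), and, up, to the amino acid and ATF4 response (0.0177), mesenchymal markers (0.0058) and extracellular matrix (0.0058), which had none without it (0.128, 0.0547, 0.0547 and 0.128). On the scaled values these 4 lists had an adjusted p = 0.649, 0.649, 0.649 and 0.692 with an estimated correlation.

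Fatty acid oxidation genes moved down as a list in Lat-M against PA (camera adjusted p = 0.0278; adjusted p = 0.851 with an estimated correlation), with a median of -0.052 and a mean of -0.15 on the log2 scale. Its only member past the test went the other way: PPARGC1B, a coactivator of mitochondrial biogenesis, rose (0.57 ± 0.11; 1 adjusted over the list alone). In Lat-M2 against PA 3 of 17 were higher and none lower (4 and 1 adjusted over the list alone, 3 and 6 scaled), with a median of 0.145 (camera adjusted p = 0.931). Proximal tubule markers also moved down (median -0.36, none of 12 past the test, none adjusted over the list alone; camera adjusted p = 0.0278, and 0.0876 scaled). Its members included ANPEP, a brush border peptidase, at 53.3 TPM in PA, 82.1 in Lat-M1 and 218 in Lat-M2, and MME, another peptidase, at 2.14, 0.0602 and 1.44 TPM. A further 3 lists had at least 3 changed members without a camera call. Fatty acid synthesis genes had 3 of 15 higher (4 higher and 1 lower adjusted over the list alone): ELOVL6, a fatty acid elongase (1.72 ± 0.21), ACSL1, an acyl-CoA synthetase (0.86 ± 0.076), and ACSS2, an acetyl-CoA synthetase (0.56 ± 0.084; camera adjusted p = 0.0547). Integrins and adhesion genes had 3 of 19 higher, VCAM1, CDH4 (2.04 ± 0.32) and MCAM (1.95 ± 0.33), and 2 lower, ITGB8 (-0.64 ± 0.11) and ALCAM (-0.43 ± 0.085; 6 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.386). MAPK output genes had 3 of 16 higher, ETV5 (0.63), SPRED1 (0.54) and MYC, and none lower (4 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.577). After scaling none was higher and 1 lower, FOSL1 (-0.58, scaled limma adjusted p = 0.0174; -0.42 and 0.0641 without scaling). Of the list members named as changed, scaling left NOP16, ELOVL6, ACSL1, VCAM1, CDH4, ITGB8 and ALCAM past the test and ended the calls of the others. The number of lists called was 0 of 31 without PA 3, where 13 were at an unadjusted p under 0.05, and 1 without Lat-M 1-1 or without Lat-M 1-2.

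Of the genes of renal cancer and metastatic latency fixed in advance, those tested missed the test in Lat-M against PA. The spread in that fit of 2 groups includes the difference between Lat-M1 and Lat-M2. A miss there does not show that a gene was unchanged in either pair, and their tests by pair are not given here. EPAS1, which encodes the hypoxia factor HIF-2 alpha, was at 0.506 ± 0.0872 TPM in PA, 2.99 ± 0.0189 in Lat-M1 and 1.05 ± 0.0633 in Lat-M2 (log2 fold change 0.93 ± 0.31, limma adjusted p = 0.127). SOX9, a transcription factor of progenitor cells, was at 21.5 ± 0.87, 44.7 ± 4.11 and 30.1 ± 3.18 TPM (0.74 ± 0.18, limma adjusted p = 0.0709). The limma adjusted p was 0.172 for HIF1A, 0.121 for the proliferation marker MKI67 and 0.202 for PAX8, a renal lineage factor. It was 0.344, 0.725 and 0.725 for the tumour suppressors SETD2, BAP1 and PBRM1. VHL, the tumour suppressor most often lost in this cancer, was between 0.0483 and 0.164 TPM in all 7 libraries, and SOX2 was at most 0.0354 TPM, so neither was tested. DKK1 was not among the listed genes and was not analysed here.

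Lat-M1 against PA asked what the first numbered pair of Lat-M libraries showed. ACTA2, smooth muscle actin, rose from 13.4 ± 0.139 TPM in PA (SD, n = 3) to 949 ± 48.2 TPM in Lat-M1 (n = 2; log2 fold change 6.04 ± 0.057, limma adjusted p = 1.31e-08). TAGLN, an actin-binding protein of smooth muscle, rose from 6.76 ± 0.812 to 421 ± 27.1 TPM (5.77 ± 0.095, limma adjusted p = 6.17e-08). RELN, a secreted matrix glycoprotein, fell from 155 ± 5.75 to 1.34 TPM (-6.06 ± 0.061), and SLC2A2, a glucose transporter of the proximal tubule, fell from 69.9 ± 1.34 to 0.17 ± 0.0842 TPM (-5.92 ± 0.066). XIST, the RNA that coats the inactive X chromosome, fell from 88.5 ± 9.25 to 0.673 TPM in Lat-M1 (-5.74 ± 0.091), while Lat-M2 was at 107 ± 3.23 TPM. The other genes named by size were PTRF (5.82), NDN (5.41) and LGALS3 (4.92), a galactoside-binding lectin, among the rises, and SULT1B1 (-5.10), a sulfotransferase, and RNU1-70P, listed at 0 in Lat-M1, among the falls. In all, 7499 genes changed, 5558 higher and 1941 lower, and 1257 of them by at least 2-fold (797 higher, 460 lower). After scaling there were 7840, 3998 higher and 3842 lower (567 and 577 by at least 2-fold). With TPM recomputed over protein-coding genes alone there were 7752, 3555 higher and 4197 lower. The count was 4679 without Lat-M 1-2.

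Gene lists of inflammation, antigen presentation and matrix rose together in Lat-M1, where the structural RNA share was 20.2% against 30.5% in PA. Examples from the lists here and below were chosen after their values were seen. NF-kB and cytokine genes were higher for 18 of 18 members (18 adjusted over the list alone), with a median log2 fold change of 1.3 (17 scaled; camera adjusted p = 7.94e-08; adjusted p = 0.91 with an estimated correlation). IL6 rose from 0.0433 to 13.5 ± 0.776 TPM, CCL2 from 2.98 ± 0.399 to 38.8 ± 5.14 TPM and the neutrophil chemokine IL8 from 22.2 ± 0.957 to 176 ± 10.7 TPM. MHC class I and antigen processing genes were higher for 17 of 17 (17 adjusted over the list alone; 15 scaled), with a median of 1 (camera adjusted p = 8e-07; adjusted p = 0.91 with an estimated correlation). HLA-B rose from 85.1 ± 6.83 to 430 ± 21.6 TPM, its partner B2M from 451 ± 18.2 to 1120 ± 63.5 TPM and the peptide transporter TAP1 from 20.5 ± 0.301 to 60.6 ± 2.19 TPM. TGF-beta targets were higher for 15 of 18 and lower for none (15 adjusted over the list alone), with a median of 1.05 (camera adjusted p = 1.37e-06; adjusted p = 0.91 with an estimated correlation). Of these, TGFBI rose from 44.3 ± 0.7 to 387 ± 12.8 TPM and THBS1, a matrix protein that activates latent TGF-beta, from 183 ± 5.14 to 1240 ± 29.8 TPM. Scaling called 1 TGF-beta target lower.

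Mesenchymal markers were higher for 10 of 12 members in Lat-M1 against PA and lower for 1 (10 and 1 adjusted over the list alone), with a median of 1.51 (camera adjusted p = 0.000224; adjusted p = 0.91 with an estimated correlation). SNAI2, a transcriptional repressor, rose from 4.33 ± 0.169 to 26.7 ± 2.98 TPM, and MMP14, a membrane metalloproteinase, was the fall, from 40.7 ± 4.68 to 16.3 ± 0.134 TPM. Extracellular matrix genes were higher for 15 of 21 and lower for 3 (15 and 3 adjusted over the list alone; camera adjusted p = 0.00132; adjusted p = 0.912 with an estimated correlation). Among them COL4A1, a basement membrane collagen, rose from 208 ± 6.57 to 914 ± 5.49 TPM and FN1, fibronectin, from 91.6 ± 3.36 to 334 ± 23.6 TPM. Integrins and adhesion genes were higher for 14 of 19 and lower for 2 (14 and 3 adjusted over the list alone; camera adjusted p = 0.00388; adjusted p = 0.912 with an estimated correlation), and the integrin chain ITGB3 rose from 9.86 ± 0.497 to 270 ± 6.55 TPM. MYC and ribosome biogenesis genes were higher for 15 of 20 and lower for 2 (16 and 2 adjusted over the list alone; camera adjusted p = 0.0324; adjusted p = 0.912 with an estimated correlation). Cytosolic ribosomal proteins were higher for 22 of 47 and lower for 1 (23 and 1 adjusted over the list alone), a call that ended on scaling (camera adjusted p = 0.0323, and 0.647 scaled; adjusted p = 0.912 with an estimated correlation).

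Lists of fat burning and of the proximal tubule moved down against the other genes in Lat-M1 compared with PA, each with members that rose. Fatty acid oxidation genes were lower for 9 of 17 and higher for 1 (10 and 1 adjusted over the list alone, 12 and 1 scaled), with a median of -0.29 (camera adjusted p = 0.000149; adjusted p = 0.912 with an estimated correlation). PPARGC1A, a coactivator that drives mitochondrial gene expression, fell from 20.1 ± 1.13 to 1.29 ± 0.0675 TPM, and CPT1A, which carries fatty acids into mitochondria, from 4.11 ± 0.305 to 1.52 ± 0.218 TPM. Proximal tubule markers were lower for 6 of 12 and higher for 3 (6 and 3 adjusted over the list alone, 8 and 1 scaled), with a median of -0.41 (camera adjusted p = 0.000844; adjusted p = 0.91 with an estimated correlation). The water channel AQP1 fell from 56.5 ± 4.09 to 3.02 ± 0.0729 TPM and the amino acid transporter subunit SLC3A1 from 126 ± 1.82 to 29.7 ± 0.308 TPM. Nuclear-encoded respiratory chain genes were lower for 16 of 57 and higher for 10 (17 and 10 adjusted over the list alone, 31 and 4 scaled). Their median was -0.0060 and their mean 0.015, while camera placed them below the other genes, whose median was 0.16 (camera adjusted p = 0.0384, and 0.000371 scaled; adjusted p = 0.912 with an estimated correlation).

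**Figure D2:**
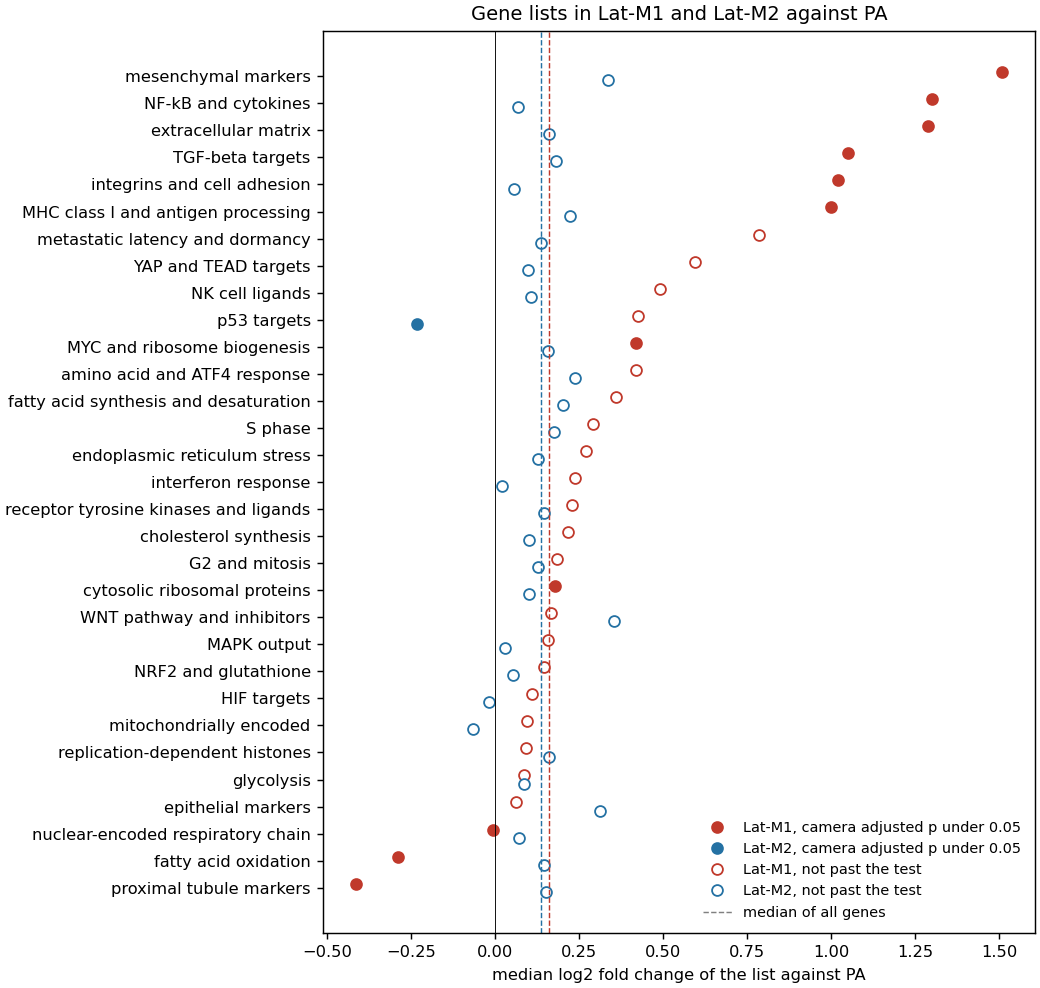
Median log2 fold change of the members of each tested gene list in Lat-M1 against PA and in Lat-M2 against PA, with filled points for camera adjusted p under 0.05 and dashed lines at the medians of all genes. NF-kB and cytokine genes lay at 1.3 in Lat-M1 and 0.067 in Lat-M2, and p53 targets at 0.43 and -0.23.

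Lat-M2 against PA showed smaller changes, led by genes that had also risen in Lat-M1. PTRF rose from 0.162 ± 0.127 TPM (SD, n = 3) to 14.2 ± 1.82 TPM (n = 2; log2 fold change 3.71 ± 0.12, limma adjusted p = 1.02e-05), SPARC by 3.28 ± 0.12 and TNFAIP6 by 3.23 on the log2 scale. POF1B, an actin-binding protein, rose from 0.503 to 17.6 TPM (3.63 ± 0.097), and NPC1L1, an intestinal cholesterol transporter, from 0.345 ± 0.0641 to 11.4 ± 0.858 TPM (3.20 ± 0.12). EDIL3 (-2.76 ± 0.084), MMP1 (-2.51 ± 0.073), AL590369.1 (-2.29) and PTGES (-2.21) were among the largest falls. COLEC12, a scavenger receptor, fell from 7.45 ± 0.705 to 0.298 ± 0.0668 TPM (-2.70 ± 0.11), where Lat-M1 stood at 8.4 ± 0.594 TPM. In all, 2494 genes changed, 2119 higher and 375 lower, and 249 of them by at least 2-fold (174 higher, 75 lower). After scaling there were 2649, 1243 higher and 1406 lower (136 and 90 by at least 2-fold). The count was 1234, 1125 and 1275 without PA 1, PA 2 and PA 3, 1558 and 1564 without Lat-M 1-1 and 1-2, and 492 without Lat-M 2-1. It was 1529 with no filter on low values, and 3767 when TPM were recomputed over protein-coding genes alone, with 2358 higher and 1409 lower.

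Targets of p53 were the only list that camera called without scaling in Lat-M2 against PA, where the structural RNA share was 25.3% against 30.5% in PA. Fry called 6 lists there, p53 targets among them (fry adjusted p = 0.0321). Of 17 members 6 were lower and none higher (10 lower adjusted over the list alone, 15 lower scaled), with a median log2 fold change of -0.23 (camera adjusted p = 2.21e-14; adjusted p = 0.977 with an estimated correlation). On the scaled values the camera adjusted p with an estimated correlation was 0.0476, close to the threshold. CDKN1A, the cyclin-dependent kinase inhibitor p21, fell from 187 ± 2.95 to 111 ± 7.63 TPM (-0.75 ± 0.062, limma adjusted p = 0.00073). TP53INP1, a stress protein, fell from 46.2 ± 0.598 to 32.1 ± 2.59 TPM (-0.51 ± 0.062) and SESN1, a sestrin, from 11 ± 0.458 to 7.6 ± 0.945 TPM (-0.49 ± 0.087). In Lat-M1 against PA the same list had 11 of 17 higher and 1 lower (11 and 1 adjusted over the list alone; camera adjusted p = 0.0519). The count of lower members in Lat-M2 was 3 without PA 3 and 3 without Lat-M 2-1, while the list's camera adjusted p stayed between 4.33e-15 and 4.49e-11 without each library in turn. The number of lists called was 1 of 31, or 2 without PA 1, 2 without Lat-M 2-1, 4 without Lat-M 2-2 and 3 after scaling.

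**Figure D3:**
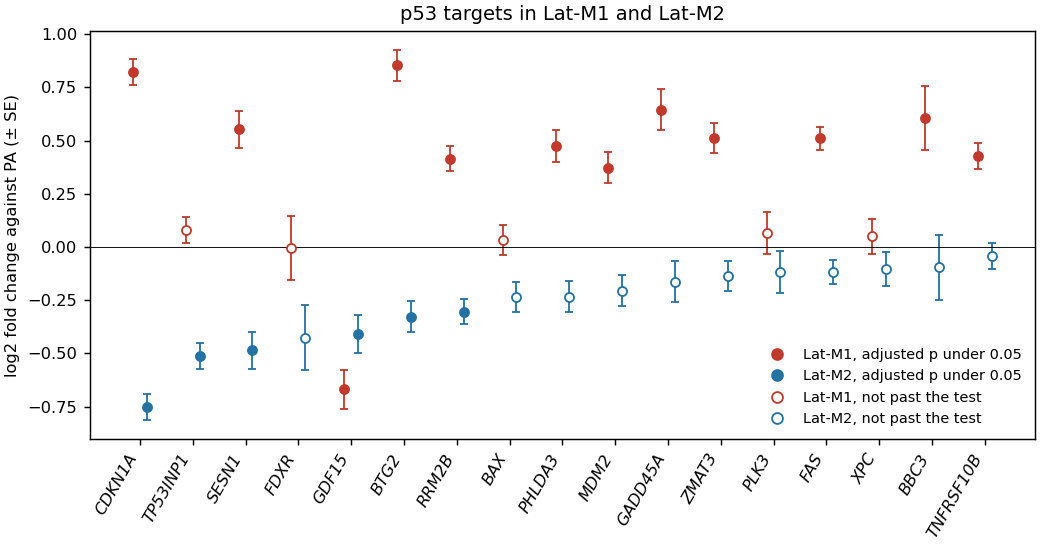
Log2 fold change of each of the 17 tested p53 targets in Lat-M1 against PA and in Lat-M2 against PA, with bars for the standard error and filled points for limma adjusted p under 0.05. CDKN1A lay at 0.82 in Lat-M1 and at -0.75 in Lat-M2.

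Several genes changed in Lat-M2 against PA without a camera call for their lists on the unscaled values. Fry did call these lists. The fry adjusted p was 0.0321 for epithelial markers, 0.00757 for mesenchymal markers, 0.0122 for proximal tubule markers and 0.0321 for integrins and adhesion genes. Epithelial markers were higher for 5 of 11 and lower for none (7 adjusted over the list alone; camera adjusted p = 0.147), with the keratin KRT18 at 278 ± 7.12 in PA and 421 ± 27.7 TPM in Lat-M2 and KRT7 at 16.7 ± 1.52 and 30.1 ± 1.28 TPM. Mesenchymal markers were higher for 6 of 12 and lower for 1 (7 and 1 adjusted over the list alone; camera adjusted p = 0.0816, and 0.0452 scaled; scaled adjusted p = 0.658 with an estimated correlation). Of these, S100A4, a calcium-binding protein of motile cells, rose from 88.5 ± 4.57 to 417 ± 20.7 TPM, while FN1 fell from 91.6 ± 3.36 to 19.6 ± 1.43 TPM. Proximal tubule markers were higher for 3 of 12 and lower for 2 (5 and 2 adjusted over the list alone, 3 and 3 scaled; camera adjusted p = 0.931), with rises of AQP1 to 268 ± 5.12 TPM and of ANPEP to 218 ± 8.4 TPM and a fall of CDH6, a kidney cadherin, from 50.3 ± 1.18 to 32.2 ± 2.4 TPM. Integrins and adhesion genes were higher for 7 of 19 and lower for 3 (8 and 4 adjusted over the list alone; camera adjusted p = 0.931), and their median of 0.056 and mean of 0.38 stood beside a camera direction of down. ITGB4, an integrin chain of hemidesmosomes, rose from 0.951 ± 0.258 to 5.09 ± 0.375 TPM, and ITGB3 fell to 4.63 ± 0.149 TPM.

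Both Lat-M pairs changed alike in 1425 genes, 1249 higher and 176 lower, where independent changes would give 704.2 and 43.52. VCAM1, TNFAIP6, SPARC and PTRF rose in both, and MMP1 and EDIL3 fell in both. After scaling there were 1305 alike, 675 higher and 630 lower, against 297.6 and 323.5 for independent changes. Of the 485 genes that differed in Lat-M as a whole, the change was larger in Lat-M1 in 348. Both comparisons used the same 3 PA libraries. In 20 simulations of unchanged groups with shared PA libraries no gene was called alike. As no gene was changed in them, that 0 does not measure the effect of sharing where many genes change. At an unadjusted p under 0.05 in limma, 2912 genes moved alike and 743 in opposite directions, against simulated means of 144 and 10.2. The simulated correlation of the 2 log2 fold changes across genes was 0.4 (observed 0.302) and their covariance was 0.0155 (observed 0.0649). Part of the overlap may therefore come from the shared libraries. The count of genes alike was 718, 677 and 772 without PA 1, PA 2 and PA 3, 837 and 722 without Lat-M 1-1 and 1-2, 322 without Lat-M 2-1, and 837 with no filter on low values.

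**Figure D4:**
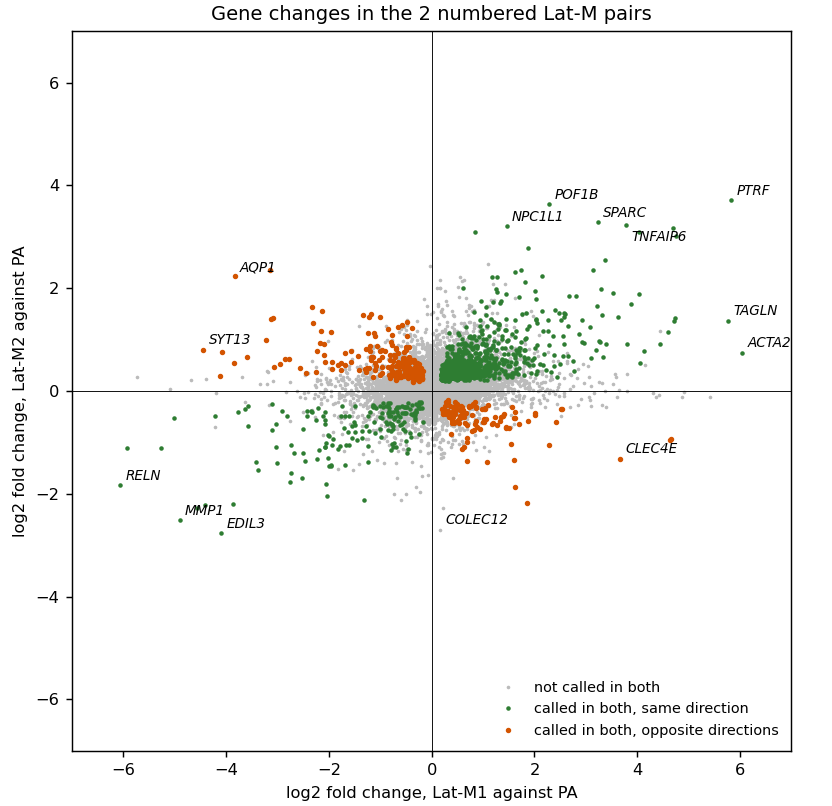
Log2 fold change against PA of each tested gene in Lat-M1 (horizontal axis) and in Lat-M2 (vertical axis), with a point per gene, coloured where both comparisons called it in the same or in opposite directions. Across 16724 genes Pearson's r was 0.302, with 1425 genes changed alike and 330 in opposite directions.

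Lat-M2 against Lat-M1 asked whether the numbered pairs differed from each other, and they did in more genes than Lat-M2 and PA. AQP1 was at 3.02 ± 0.0729 TPM in Lat-M1 and 268 ± 5.12 TPM in Lat-M2 (SD, n = 2 each; log2 fold change 6.06 ± 0.076, limma adjusted p = 4.37e-08). XIST (6.01), SYT13 (5.24), a synaptotagmin, SULT1B1 (5.14) and USH1C (4.91), a scaffold protein of microvilli, were the next largest on the side of Lat-M2. ITGB3 was at 270 ± 6.55 TPM in Lat-M1 and 4.63 ± 0.149 TPM in Lat-M2 (-5.59 ± 0.069, limma adjusted p = 4.37e-08). NDN (-5.53), ACTA2 (-5.29), PHGDH (-4.98), the first enzyme of serine synthesis, and CLEC4E (-4.98), a receptor for damaged cells and mycobacteria, were also lower in Lat-M2. In all, 6022 genes differed, 2668 higher in Lat-M2 and 3354 lower, and 1123 of them by at least 2-fold (575 higher, 548 lower). After scaling there were 7376, 3603 higher and 3773 lower (580 and 510 by at least 2-fold). With TPM recomputed over protein-coding genes alone there were 7536, 4516 higher and 3020 lower. The count was 3947 without Lat-M 1-1 and 3815 without Lat-M 1-2.

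In Lat-M2 against Lat-M1, camera called 11 of 31 lists, 8 lower and 3 higher in Lat-M2, where the structural RNA share was 25.3% against 20.2% in Lat-M1. NF-kB and cytokine genes were lower for 17 of 18 (17 adjusted over the list alone; camera adjusted p = 5.14e-10; adjusted p = 0.735 with an estimated correlation), with IL6 at 13.5 ± 0.776 in Lat-M1 and 0.313 ± 0.0711 TPM in Lat-M2. MHC class I genes were lower for 14 of 17 (14 adjusted over the list alone; camera adjusted p = 2.62e-08; adjusted p = 0.735 with an estimated correlation), with HLA-B at 430 ± 21.6 and 111 ± 8.88 TPM. TGF-beta targets were lower for 12 of 18 (15 adjusted over the list alone; camera adjusted p = 2.05e-07) and p53 targets for 13 of 17 (14 lower and 1 higher adjusted over the list alone; camera adjusted p = 3.16e-06), each with an adjusted p = 0.735 with an estimated correlation. CDKN1A was at 332 ± 16 TPM in Lat-M1 and 111 ± 7.63 TPM in Lat-M2. Integrins were lower for 15 of 19 and higher for 2 (15 and 3 adjusted over the list alone; camera adjusted p = 9.4e-05), matrix genes lower for 14 of 21 and higher for 3 (14 and 3 adjusted over the list alone; camera adjusted p = 0.000233) and mesenchymal markers lower for 7 of 12 and higher for 2 (7 and 2 adjusted over the list alone; camera adjusted p = 0.00474). These 3 lists also had an adjusted p = 0.735 with an estimated correlation. FN1 was at 334 ± 23.6 TPM in Lat-M1 and 19.6 ± 1.43 TPM in Lat-M2.

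Genes of metastatic latency and dormancy were lower for 10 of 16 members in Lat-M2 than in Lat-M1 and higher for 4 (10 and 4 adjusted over the list alone; camera adjusted p = 0.0356; adjusted p = 0.925 with an estimated correlation). BHLHE41, a transcription factor, was at 2.29 ± 0.298 TPM in PA, 39 ± 4.13 in Lat-M1 and 2.03 ± 0.097 in Lat-M2, whereas NR2F1, a nuclear receptor, was at 4.9 ± 0.17, 0.733 ± 0.15 and 4.45 ± 0.471 TPM. Against PA the same list had 10 of 16 higher and 4 lower in Lat-M1 (10 and 4 adjusted over the list alone, 10 and 5 scaled; camera adjusted p = 0.106, and 0.0348 scaled; scaled adjusted p = 0.463 with an estimated correlation) and 5 higher and 1 lower in Lat-M2 (5 and 2 adjusted over the list alone; camera adjusted p = 0.931). The lists higher in Lat-M2 than in Lat-M1 were fatty acid oxidation, with 10 of 17 higher and 1 lower (11 and 2 adjusted over the list alone; camera adjusted p = 0.000494; adjusted p = 0.735 with an estimated correlation), proximal tubule markers, with 7 of 12 higher and 2 lower (8 and 2 adjusted over the list alone; camera adjusted p = 0.0016; adjusted p = 0.735 with an estimated correlation), and the respiratory chain, with 17 of 57 higher and 7 lower (17 and 7 adjusted over the list alone; camera adjusted p = 0.0464; adjusted p = 0.925 with an estimated correlation). PPARGC1A was at 1.29 ± 0.0675 TPM in Lat-M1 and 22.1 ± 0.638 TPM in Lat-M2, and SLC3A1 at 29.7 ± 0.308 and 143 ± 5.92 TPM.

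Lists of markers of other cell types had low medians, while some members were expressed. The median TPM of PA, Lat-M1 and Lat-M2 was 0.00977, 0.028 and 0.0183 for 12 fibroblast and pericyte markers and 0.00256, 0.00638 and 0.00865 for 8 endothelial markers. It was 0.0596, 0.129 and 0.157 for 9 leukocyte markers, 0, 0.0815 and 0 for 3 erythroid markers, and 0.241, 0.0305 and 0.357 for 8 neural and glial markers. A mean of at least 1 TPM was reached in PA, Lat-M1 and Lat-M2 by 3, 3 and 3 of the fibroblast and pericyte markers (ACTA2, COL1A1 and RGS5), 1, 1 and 1 of the endothelial, 2, 2 and 2 of the leukocyte, none of the erythroid and 2, 3 and 2 of the neural and glial markers. These lists had fewer than 5 tested members and were not tested.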

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

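The tests of scaling, of structural RNAs, of fibroblasts and of another cell line were chosen after the results were seen, as were the list tests of Lat-M1 and of Lat-M2 against PA.

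The difference between the numbered Lat-M pairs stood out most. In 330 genes the pairs moved in opposite directions against PA, 107 up in Lat-M1 and down in Lat-M2 and 223 the reverse. After scaling there were 615 such genes. The number that independent changes would give was not computed here, so these counts do not show an excess. All 330 also differed between the pairs by limma, which follows from opposite calls in the same fit and is no separate support. Between the pairs 11 gene lists differed by camera, none of them with an estimated correlation (0 of 31 at an unadjusted p under 0.05; fry called 15). AQP1 rose in Lat-M2 and fell in Lat-M1 against PA, with a difference of 6.06 on the log2 scale, and SYT13, at 22.9 TPM in PA, 0.0969 in Lat-M1 and 40.6 in Lat-M2, differed by 5.24. ITGB3 differed the other way (-5.59), as did CLEC4E (-4.98), at 27.2 TPM in PA, 355 in Lat-M1 and 10.3 in Lat-M2.

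A single library stood apart from the other 3 Lat-M libraries in PBRM1, with a gap of 0.872 of the range (Lat-M 2-1 at 26.9 TPM), past Dixon's 95% critical value for 4 samples. Chance gives about 1 in 20, and 81 named genes were examined.

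For the number of genes that differed between Lat-M and PA, only the real split (1 split) of the 35 splits of the 7 libraries into 3 and 4 gave as many as 485, and the highest other split gave 1. This excludes chance only if the 7 libraries are exchangeable, and libraries of a Lat-M number were correlated (consensus 0.598). The count was 88 with that correlation and 3 with averaged libraries, so chance between the Lat-M numbers was not excluded. With the last number as a block it was 0 (2060 at an unadjusted p under 0.05 in limma). That block leaves PA 3 alone and does not separate the Lat-M numbers, so it does not bear on this question.

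More genes were higher than lower in both Lat-M pairs against PA. With the structural RNAs RN7SL1, RN7SL2, RN7SK and RMRP left out and the other genes rescaled to the same sum, the median log2 fold change of all genes came to -0.0151 in place of 0.16 in Lat-M1 and to 0.0455 in place of 0.137 in Lat-M2, which is consistent with their smaller share raising the TPM of the other genes. Of the genes called, 48.1% were then higher in Lat-M1 and 63.6% in Lat-M2. A trend on GC content or transcript length stays open: 73.6% of the genes called in Lat-M1 were higher after its removal, but the removal kept the median of all genes (0.162 before, 0.156 after) and with it the share. Whether the cells or the library preparation differed in these RNAs was not tested.

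The joint rise of mesenchymal, NF-kB, TGF-beta and MHC class I genes in Lat-M1 was weighed against admixed fibroblasts or pericytes, which would bring their abundant collagens, but the highest of COL1A2, COL3A1, DCN and LUM in a Lat-M1 library reached 0.00403% of the rise of ACTA2, and their highest values in a Lat-M1 library were 0, 0.0276, 0.0364 and 0.0326 TPM. Of the 11 markers on the list beside ACTA2 only COL1A1 reached 1% of that rise (up to 20.6 TPM, 2.29%), without the COL1A2 that fibroblasts make with it, so the exclusion rests on the other markers. With the GC and length trend removed, the median of the 65 members kept 98.7% of its value (1.11 before, 1.09 after). VHL stayed at 0.139 TPM or less in Lat-M1, which leaves open another cell line that also lacks VHL, so such a line and a state of the same cells cannot be told apart from expression. A biological difference between the Lat-M pairs remains a hypothesis that was not tested, and library kit was not tested because the kit of each library is not stated.

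The lower p53 targets in Lat-M2 were weighed against scaling and sequence composition. A scaling factor moves all genes of a library alike, but the median of the p53 targets lay at -0.37 relative to that of all genes, with 17 of 17 members below it (by 0.18 to 0.89). Camera compares a list with the other genes, so its call already rested on this gap. These values restate that call and are no separate support. With the GC and length trend removed, the median relative to all genes kept 97.7% of its value (-0.37 before, -0.36 after). A biological difference between Lat-M2 and PA remains open as a hypothesis that was not tested.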

How the results depend on the processing

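Scaling by the median ratio, rescaling to protein-coding genes and the list tests of Lat-M1 and of Lat-M2 against PA were chosen after seeing the data. No result for a named gene reversed under an alternative that was run on it, which was 145 results for most, 138 for protein-coding genes, 124 for a mean of at least 5 TPM, 64 for the alternatives of Lat-M against PA alone and 19 for those of Lat-M2 against Lat-M1. Genes named by size had groups that did not overlap, so leaving out a library or changing the pseudocount or filter could not reverse them. Some other results were examples chosen after their values were seen. The absence of reversals was thus largely fixed by the choice of genes. A pseudocount of 0.1 kept 140 of 145 on the same side of the threshold, no filter 121, scaling 129, and leaving out a library 111 to 133. The test against a 1.5-fold change kept 101 of 145. Of the 64 results of Lat-M against PA, duplicateCorrelation kept 49, averaged libraries 28 and the last number as a block 25, and those not kept lost their calls. The fit of 3 groups kept 43 of the 64 and gave calls to the other 21. With no filter on low values, which adds genes to the adjustment, the counts of changed genes were 107 (Lat-M), 1529 (Lat-M2) and 837 (alike). At 2-fold or more they were 121 (Lat-M), 1257 (Lat-M1), 249 (Lat-M2), 1123 (Lat-M2 against Lat-M1) and 124 (alike), and against a 1.5-fold change 14, 1196, 125, 963 and 82, each a stricter criterion by construction. Without each library in turn the ranges were 18 to 1861 (Lat-M), 4679 to 7932 (Lat-M1), 492 to 3162 (Lat-M2), 3815 to 5852 (Lat-M2 against Lat-M1) and 322 to 1911 (alike), where a lone library of a pair was assumed to vary like the other groups. The lowest were without PA 2, Lat-M 1-2, Lat-M 2-1, Lat-M 1-2 and Lat-M 2-1, and the highest without Lat-M 2-2, except 5852 without PA 1. Lat-M against PA gave 6106 genes in the fit of 3 groups, whose spread leaves out the difference between the pairs, 88 with duplicateCorrelation (consensus correlation 0.598), 3 with averaged libraries and 0 with the last number as a block (2060 at an unadjusted p under 0.05 in limma). Scaling gave 208 for Lat-M, and protein-coding genes alone gave 3767 for Lat-M2; the cause was not tested.

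On the unscaled values, camera at an estimated correlation called 0 lists in each of the 4 comparisons, with 0, 0, 1 and 0 of 31 at an unadjusted p under 0.05. On the scaled values, p53 targets in Lat-M2 against PA had an adjusted p = 0.0476 in that test. Fry called 10 (Lat-M), 23 (Lat-M1) and 6 (Lat-M2). For Lat-M all 10 were up, and of the 6 lists that camera called, fry called only MYC and ribosome biogenesis. Camera at the preset correlation called 3 lists for Lat-M2 after scaling, and the cause was not tested. Without each library in turn the ranges were 0 (without PA 3) to 9 (without PA 1 or Lat-M 2-2) for Lat-M, 9 to 13 for Lat-M1, 1 to 4 (without Lat-M 2-2) for Lat-M2 and 10 to 14 for Lat-M2 against Lat-M1. Not run, because the files hold no counts, were TMM, RLE and upper-quartile normalization, the count filters, the DESeq2 Wald test and camera under RLE scaling. No depth is given, so what depth limits could not be assessed.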

Other observations

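The tests of runs of neighbouring genes in Lat-M2, of their number on each chromosome and of lists in Lat-M1 and in Lat-M2 against PA were chosen after results were seen.

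HIF targets and glycolysis genes went both ways in Lat-M1 against PA and had no camera call there. HIF targets were higher for 8 and lower for 6 of 22 in Lat-M1 against PA (8 and 7 adjusted over the list alone, 8 and 9 scaled; camera adjusted p = 0.661), with the carbonic anhydrase CA12 up from 0.483 ± 0.0308 to 3.64 ± 0.279 TPM and VEGFA up from 8.25 ± 0.387 to 11.8 ± 0.428 TPM, but the glucose transporter SLC2A1 down from 138 ± 6.56 to 89.6 ± 4.92 TPM and ENO2, an enolase, down from 24.3 ± 0.38 to 10.4 ± 0.107 TPM. In Lat-M2 against PA 2 were higher and 2 lower (2 and 2 adjusted over the list alone; camera adjusted p = 0.104, and 0.0191 scaled, with 9 lower; scaled adjusted p = 0.658 with an estimated correlation). Glycolysis genes were higher for 6 and lower for 4 of 20 in Lat-M1 (6 and 4 adjusted over the list alone, 6 and 9 scaled; camera adjusted p = 0.583), and 1 was higher in Lat-M2 (none adjusted over the list alone; none higher and 4 lower scaled). No mitochondrially encoded gene of 13 passed in either pair, over all genes or adjusted over the list alone (camera adjusted p = 0.62 and 0.0816). Cholesterol synthesis genes were higher for 11 and lower for 1 of 23 in Lat-M1 (12 and 1 adjusted over the list alone, 10 and 4 scaled; camera adjusted p = 0.0628) and higher for 4 in Lat-M2 (4 adjusted over the list alone; 3 higher and 3 lower scaled), and NRF2 and glutathione genes were higher for 6 and lower for 7 of 22 in Lat-M1 (7 and 7 adjusted over the list alone, 3 and 9 scaled; camera adjusted p = 0.258).

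The following further lists had no camera call in Lat-M1 against PA without scaling. Amino acid and ATF4 response genes were higher for 13 and lower for 3 of 19 (14 and 3 adjusted over the list alone; camera adjusted p = 0.0628, and 0.0314 scaled; scaled adjusted p = 0.283 with an estimated correlation), endoplasmic reticulum stress genes higher for 8 and lower for 1 of 15 (9 and 2 adjusted over the list alone, 5 and 5 scaled; camera adjusted p = 0.499) and YAP and TEAD targets higher for 11 and lower for 4 of 16 (camera adjusted p = 0.182). S phase genes were higher for 11 and lower for 1 of 21 (7 and 5 scaled; camera adjusted p = 0.218) and G2 and mitosis genes higher for 11 and lower for 3 of 23 (4 and 7 scaled; camera adjusted p = 0.499). Interferon response genes were higher for 7 and lower for 1 of 17 (8 and 1 adjusted over the list alone, 6 and 3 scaled; camera adjusted p = 0.448), NK cell ligands higher for 10 and lower for 2 of 12 (camera adjusted p = 0.114), receptor tyrosine kinases and ligands higher for 11 and lower for 5 of 21 (12 and 5 adjusted over the list alone, 8 and 7 scaled; camera adjusted p = 0.499) and WNT pathway genes higher for 3 and lower for 2 of 7 (camera adjusted p = 0.864). Replication-dependent histones were higher for 4 and lower for 4 of 21 (camera adjusted p = 0.371), with 8 lower and none higher after scaling. For the YAP, S phase, G2, NK cell ligand, WNT and histone lists the counts adjusted over the list alone were those over all genes.

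Changes in Lat-M1 followed chromosomes, which is consistent with gained or lost copies in these libraries, while another cell line or a mix-up cannot be told apart from that by expression alone. Genes on chromosome 15 had a median 0.445 above that of all genes on the log2 scale, with 68.8% of 552 genes higher, and chromosomes 5 (0.255), 22 (0.248) and 6 (0.204) were also over 0.2 above (each permutation p = 1e-04, the smallest that 10000 permutations can give, adjusted p = 0.00015), while 14 (-0.2), 13 (-0.19) and X (-0.139) lay furthest below (adjusted p = 0.00015 each). Of 305 runs of 50 neighbouring genes, 18 lay beyond the furthest run of 1000 shuffled orders (0.333), 15 above all genes and 3 below, the furthest at 0.76 on chromosome 6 between SLC35B3 and E2F3-IT1 (38 genes higher, 4 lower), and at -0.674 on chromosome 4 between ZNF718 and RGS12 (none higher, 36 lower). The MHC class I list kept 78.5% of its median when each gene's chromosome median was taken off (0.842 before, 0.661 after), so its rise was not accounted for by whole chromosomes; copy number was not measured, and coordinated regulation was not tested.

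In Lat-M2 no chromosome passed the 0.2 set for a gain or loss, but the furthest, chromosome 12, had a median 0.172 above that of all genes (adjusted p = 0.00026), with 43.1% of its genes higher and 1.27% lower. Chromosomes 2, 5, 7, 10, 11, 15, 16 and 21 had the same adjusted p, and chromosome 16 stood at 0.141. All 17 runs of 50 neighbouring genes on chromosome 12 lay above all genes. Of the 14 runs beyond the furthest shuffle (0.185), 9 were on chromosome 12, and 13 of the 14 were above and 1 below. The 2 Lat-M2 libraries stood at 0.173 and 0.172 and the PA libraries at -0.0126 to 0.0122, so the 0.2 was too high to exclude a small shift of a whole chromosome, such as a gain in some cells, and this stays open. The furthest run was at 0.283 on chromosome 16 between POLR3K and CRAMP1L, under the 0.3 set for a gain, so a part of a chromosome gained in some cells and regulation of neighbouring genes cannot be told apart.

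Loss of XIST in Lat-M1 could have gone with a rise of X-linked genes, but these had a median of -0.139 relative to all genes on the log2 scale, below and not above the rest.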
